A study of Oryza sativa with 3 samples.

How the data were processed

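Total RNA from rice stems, 5 stems for each sample, was labelled with biotin from 6 µg by the Affymetrix protocol and measured on 3 arrays, per the labels' protocols. The groups were taken from the sample titles: 2 arrays of stems infested by a striped stem borer larva for 24 h and 1 array of insect-free stems. The plants were kept at 26 °C with 12 h of light during the treatment. The series describes the infested samples as replicate biological experiments, and the control has 1 sample. The name of the array design is not given in the sources used here.

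The intensity values were computed with MAS5, per the submitters' processing notes, which give no version, and were scaled array by array, per the file headers. The 2% trimmed mean of the deposited intensities was 497.3 on the control array and 497.7 on each infested array. The deposited table also gives a detection p-value for each probe set and array and a change p-value for each infested array against the control, computed by the authors. The log2 values in it are signal log ratios of each infested array over the control, also computed by the authors, per the file headers. Its change calls used different limits in the comparisons: the largest change p-value called increased was 0.004481 for infested replicate 1 and 0.001832 for replicate 2. These calls numbered 6517 increased and 6760 decreased for replicate 1 and 4145 and 5343 for replicate 2, and they were set beside the counts and entered no test. In the authors' deposited table, 3604 probe sets were called increased in both comparisons, 4359 decreased in both and 37 in opposite directions. A further deposited table held the same intensities, with 0 differing values. The 3 columns of detection calls were not used because 2 of their headers did not name a sample, and detection p-values were used in their place.

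Of 57318 probe sets, 60 array controls were left out. The platform annotation used here paired 22436 of the other 57258 with 1 gene symbol (17905 genes) and 95 with several, and 34787 had no listed symbol. All 22436 gene identifiers were found in a RefSeq gene table (assembly ASM3414082v1), which was used for synonyms. Product titles stand in the deposited table for 37474 probe sets. A probe set with several symbols was given no gene name, and one without a symbol is described by its title. Median intensities were 85.1, 74.2 and 85.8 in the control and infested replicates 1 and 2. The number of arrays limits the precision: the median standard error of a log2 difference was 0.33 for probe sets with intensities over 1000 and 1.31 for those under 100.

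The log2 intensities of probe sets with a detection p-value under 0.05 on at least 1 array were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes come from this fit. It has 1 residual degree of freedom, from the infested arrays, to which eBayes adds 12 prior degrees of freedom from the other probe sets. The lone control is assumed to vary like the infested arrays. The trend sets the spread by the mean intensity over the 3 arrays. A probe set bright in infested stems and undetected in the control is thus given the small standard error of a brighter one. Probe sets at least 2-fold from the control in both infested arrays were also counted, with no test. A probe set not detected on any array of the lower group has only a bound there. Its fold is given as at least the ratio of the mean log2 intensity of the higher group to that of the lower group, in which each value was raised to the lowest detected intensity of its array where it lay under it (22.1, 25.6 and 29.8). Probe sets of higher intensity were also undetected, among them LIS (LOC4328124) at 153.5 in the control. Where an undetected value lay above the lowest detected intensity, as for LIS, the fold is the plain ratio. A fold written as at least is thus a convention for undetected values and not a lower limit. The true fold can be smaller. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

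Before the data were examined, the test, the filter, 28 gene lists, 25 key genes, the rule for named genes and the alternative settings were fixed. Lists were filled by product titles, symbols and synonyms, so a title can bring in a relative of the named family: the peroxidase list holds a glutathione peroxidase. The lists were tested with limma's camera at a preset correlation of 0.01, 1 probe set for each gene (that with the highest mean log2 intensity), adjusted over the lists with at least 5 measured members. The named genes were the 12 largest rises and 12 largest falls past the threshold with 1 gene name, the 4 members of each list with the smallest p, and the key genes. Of the key genes 14 were matched by synonym. PR1a and MPK6 were matched later by title or synonym, and T5H and RERJ1 were added after the data were examined. The intensities of a further probe set of LOC4337276 and of LOC4348646, given because the titles conflict, and the terpene synthase LOC4335526 were chosen after their values were seen. A list of diterpenoid phytoalexin genes matched by synonym was added before any test was run, and 15 further families after the main results were seen, and the 16 were adjusted among themselves.

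The alternatives were quantile normalization, median centring, 16 added to the intensity, a floor of 64 under it, no detection filter, detection on all 3 arrays, no intensity trend, a robust variance, at least 2-fold as well as the p threshold, a 3-fold limit for the untested counts, leaving out each infested replicate, and for the lists an estimated correlation, fry, ranks and all probe sets of a gene. No intensity trend with detection on all 3 arrays, and a mean intensity of at least 64, were added after seeing the data. Camera with an estimated correlation, and fry, rest on the 1 residual degree of freedom of the fit, which leaves them little power.

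The limma step was tested on simulated values for the 27446 probe sets of the comparison, with the fitted spread, over 5 draws. The simulated control had the same spread as the infested arrays, so the rates below hold only if the real control varies like them. With 5489 probe sets changed, it recovered 14.0% of changes of 1 on the log2 scale, 58.4% of changes of 2 and 73.6% of changes of 3, and 5.08% of its calls were false. With 200 changed, it recovered 1.71%, 25.9% and 55.0%, and 26.8% of its calls were false. In the first case 64.1% of calls under an intensity of 64 were false and 3.97% of the others, and in the second 100% and 23.1%. With no change it made at most 45 calls. In the real comparison 33 of 4260 calls had a mean intensity under 64.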

Results

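Gene expression was measured in rice stems (Oryza sativa, cultivar Xiushui 11) with 3 Affymetrix arrays, 1 array for each sample. The striped stem borer (SSB, Chilo suppressalis) is a moth whose larvae bore into rice stems and feed inside them. In the infested group each plant received 1 larva of instar 3 that had been starved for 2 h, and damaged stems were harvested after 24 h. The group had 2 arrays, described in the series as biological replicates, and the insect-free group had 1 array. Each RNA sample came from 5 stems. Of the 57258 probe sets that are not array controls, 23206 (40.5%) were detected on the control array, 24020 (42.0%) on infested replicate 1 and 21990 (38.4%) on infested replicate 2. The number of arrays limits the precision of every value below, and the control group has no replicate.

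The comparison of infested with control stems asks which rice genes respond to larval feeding within a day. In the infested stems 8 of 10 genes in a list matched to jasmonate synthesis by title or name, 8 of 15 genes in the list of its JAZ repressors, 30 of 63 genes of pathogenesis-related proteins, 10 of 24 genes in the protease inhibitor list, 5 of 10 terpene genes and 4 of 8 dehydrin and related genes rose, while 3 pathogenesis-related, 1 of the protease inhibitor list and 1 terpene gene fell. Of core histones 9 of 26 genes fell, of cell division genes 7 of 52 and of photosynthesis genes 8 of 30, where 1 rose. These 9 lists passed the camera test at its preset correlation of 0.01 and did not with an estimated correlation (adjusted p = 0.462 for each). The latter test rests on 1 residual degree of freedom and has little power, while the preset correlation is assumed. Neither result shows how far correlated genes drive the calls. RAB21 (LOC4350454), a dehydrin that accumulates in drying or abscisic acid-treated rice, had an intensity of 4.8 in the control, where it was not detected. It was at 29390 ± 11400 (SD, n = 2) in infested stems, at least 1280-fold higher (limma adjusted p = 1.63e-09), and a further probe set was at least 155-fold higher. The fitted standard error, 0.378 on the log2 scale, does not measure the noise of the undetected control value. Here and below, a fold written as at least follows a convention for undetected values. It is not a lower limit, and the true fold can be smaller. The trypsin inhibitor RBBI3.3 (LOC9271230) rose 38.7-fold, from 909.3 to 35480 ± 6340 (SD, n = 2), and the rbcS gene LOC4351966, for the small subunit of Rubisco, was 4.77-fold lower, with 35965.7 in the control and 7578 ± 1180 (SD, n = 2) in infested stems. A further probe set titled as the small subunit of Rubisco was 2.34-fold lower.

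Among 27446 probe sets detected on at least 1 array, 2254 rose and 2006 fell in infested stems (limma with an intensity trend, Benjamini-Hochberg adjusted p under 0.05), 15.5% of those tested. The rises covered 1596 named genes and the falls 1441. At least 8-fold rises in both infested arrays were seen for 531 of these probe sets and falls of that size for 85. Of the rises, 634 were not detected in the control, and 124 of the falls were not detected on either infested array. For those 634 the p-value rests on a single undetected control value, whose noise the fit does not measure. The authors' deposited table calls 2066 of the rises increased, and 1958 of the falls decreased, in both of its array-against-control comparisons. The count depended on the settings: limma without the intensity trend called 0 probe sets and so did limma with the trend and a floor of 64 under the intensities, against 5276 and 5879 at an unadjusted p under 0.05, while without the trend 2657 were called among probe sets detected on all 3 arrays, a setting chosen after seeing the data. The residual spread has 1 degree of freedom, from the infested arrays alone, and the lone control array is assumed to vary like them.

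Without any test, 3104 probe sets were at least 2-fold higher than the control in both infested arrays and 3081 at least 2-fold lower, against 4481 that differed at least 2-fold between the infested replicates. Among the 18986 probe sets detected on all 3 arrays the counts were 1630 higher, 1820 lower and 1185 apart between replicates. Both differences share the control array. Simulated arrays with no change gave on average 1833 probe sets at least 2-fold the same way in both (highest of 5 draws 1863), against 6185 observed. Independent lists of these sizes would share 624.8 higher and 922.2 lower probe sets. The independent lists leave out the shared control, which the simulated arrays include. The simulated control was given the spread fitted from the infested arrays. A control array that varied more would also raise the count, so the excess alone does not show a response.

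**Figure D1:**
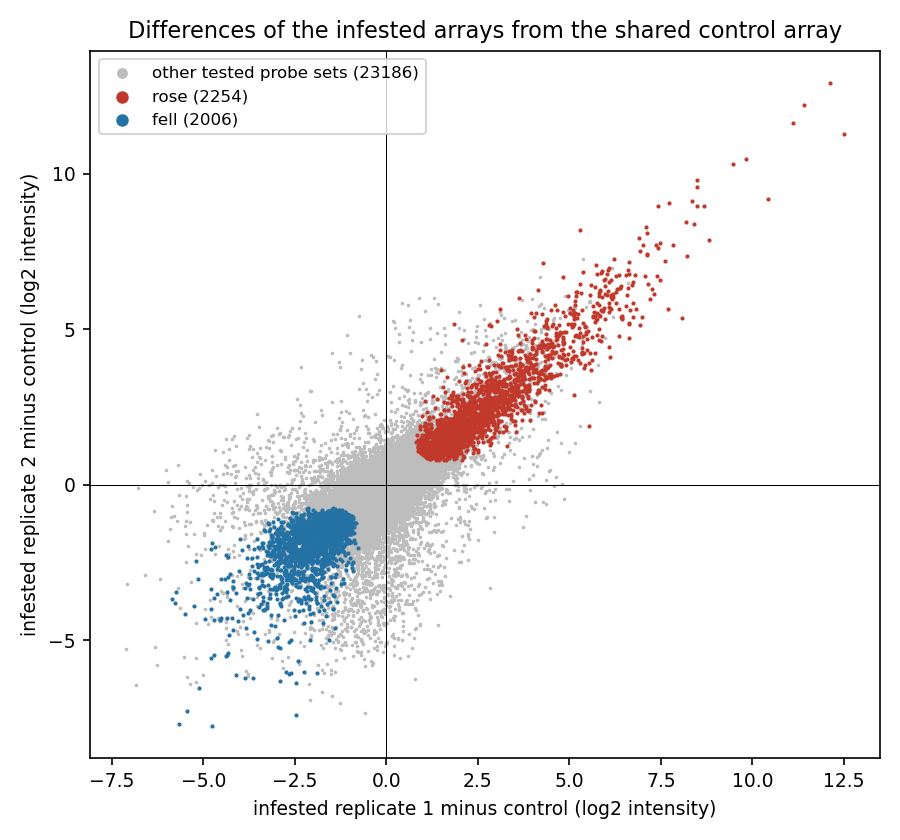
Log2 intensity of infested replicate 1 (x axis) and infested replicate 2 (y axis), each minus the shared control array, for 27446 tested probe sets. Red points are the 2254 rises, blue points the 2006 falls and grey points the rest; red points extend further from 0 than blue ones.

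Jasmonate, the hormone of wound responses, is made from fatty acids by lipoxygenases, allene oxide synthase and cyclase, and a 12-oxophytodienoate reductase. Of 10 genes in the jasmonate biosynthesis list, 8 rose and none fell (9 rose when adjusted over the list alone), with a median log2 change of 2.80 (camera adjusted p = 1.522e-09, 0.462 with an estimated correlation). The lipoxygenase LOX1.1 (LOC4334049), titled lipoxygenase L-2 in the deposited table, rose 37.9-fold, from 243.1 to 9272 ± 1590 (SD, n = 2), and the lipoxygenase rci-1 (LOC4352505) rose 6.65-fold. The reductases OPR5 (LOC4340485) and OPR1 (LOC4340490) rose 18.3-fold and 17.2-fold. Lipoxygenase L-2 is known as a 9-lipoxygenase, and OPR1 and OPR5 belong to the reductase class outside jasmonate synthesis. The allene oxide synthase AOS1 (LOC4334233) rose 4.23-fold. Outside the list, OPR7 (LOC4345762), the reductase of jasmonate synthesis, rose 2.38-fold and JAR1 (LOC4339756), which joins jasmonate to isoleucine, 3.89-fold. The allene oxide cyclase AOC (LOC4333201) did not pass the test, at 9658.7 in the control and 17020 ± 1770 (SD, n = 2) in infested stems (adjusted p = 0.122), nor did AOS2 (LOC4332121, log2 difference 0.03 ± 0.73 SE).

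JAZ proteins repress jasmonate signalling and are themselves induced by it. In the JAZ list 8 of 15 genes rose and none fell (9 adjusted over the list alone), with a median log2 change of 1.16 (camera adjusted p = 5.041e-08, 0.462 with an estimated correlation). The median was 0.73 with detection on all 3 arrays. Of the 15, 3 are GATA factors that share the TIFY name and are not JAZ repressors. JAZ9 (LOC4331832) was at least 22.5-fold higher, JAZ11 (LOC4331833) rose 14.4-fold and LOC4347164, with the synonym OsJAZ7, 10.3-fold. RERJ1 (LOC4335417), a jasmonate-induced transcription factor, rose 11.0-fold, while the jasmonate receptor COI1a (LOC4324818) had a log2 difference of 0.38 ± 0.32 (SE; adjusted p = 0.521).

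Pathogenesis-related proteins and chitinases, of which the chitinases attack the walls of fungi, formed the list with the smallest p. In it 30 of 63 genes rose and 3 fell (36 and 7 adjusted over the list alone), with a median log2 change of 1.27 (camera adjusted p = 3.284e-11, 0.462 with an estimated correlation). The chitinases LOC4351188 and LOC4346052 were not detected in the control and were at least 149-fold and 108-fold higher in infested stems. The PR10 protein LOC4352487 rose 18.9-fold, and PBZ1 (LOC4352491), the probenazole-inducible PR10 protein, rose 5.21-fold from an already high 8770. PR1a (LOC4342317) rose 2.69-fold (adjusted p = 0.0405), with the infested replicates at 6944.2 and 2873.3, and lost its call with quantile normalization (limma adjusted p = 0.101) and with a robust variance (0.189).

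Protease inhibitors block the digestive enzymes of feeding insects, and 10 of 24 genes in their list rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 change of 0.95 (camera adjusted p = 1.431e-05, 0.462 with an estimated correlation). The medians were 1.00 and 1.49 in infested replicates 1 and 2, and 0.60 without a detection filter. Besides RBBI3.3, a probe set titled Bowman-Birk inhibitor rose 13.6-fold to 39240 ± 2820 (SD, n = 2) and the proteinase inhibitor LOC4331501 rose 15.5-fold. Some members of the list are lipid transfer proteins that share its title words. WRKY transcription factors, regulators of defence genes, rose in 11 of 29 cases and fell in none (12 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 3.095e-06, 0.462 with an estimated correlation). LOC4339739, titled WRKY17 in the deposited table, rose 16.8-fold and WRKY71 (LOC4328512) 5.26-fold.

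In the terpene list 5 of 10 genes rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 change of 2.69 (camera adjusted p = 9.422e-06, 0.462 with an estimated correlation). Without a detection filter that median was 0.95, and with detection on all 3 arrays 3.77. A probe set titled as similar to a sesquiterpene synthase rose 29.4-fold, from 1451.4 to 42730 ± 1070 (SD, n = 2). The terpene synthase LOC4335526 rose 6.21-fold, from 5836.3 to 36230 ± 95.5 (SD, n = 2). Outside the list, the linalool synthase LIS (LOC4328124), which makes a volatile released by damaged rice, was at least 23.9-fold higher. The diterpene synthase KSL4 (LOC4335094), of momilactone synthesis, was at least 11.2-fold higher but was detected on infested replicate 1 alone. CPS4 (LOC4335090) did not pass the test (adjusted p = 0.0829), though it did at a mean intensity of at least 64 (limma adjusted p = 0.0387), a setting chosen after seeing the data. Phenylpropanoid genes, for lignin and phenolic compounds, rose in 8 of 19 cases and fell in 1 (8 and 2 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 8.197e-04, 0.462 with an estimated correlation). The cinnamoyl-CoA reductase LOC4327909 rose 26.3-fold and the phenylalanine ammonia-lyase PAL06 (LOC4330040) 3.67-fold. In the tryptophan and serotonin list 3 of 6 genes rose and none fell (3 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.0231, 0.462 with an estimated correlation). Its probe set titled aromatic amino acid decarboxylase rose 14.8-fold and the tryptophan synthase beta subunit LOC4344612 2.23-fold. T5H (LOC4351945), a cytochrome P450 that makes serotonin from tryptamine, rose 2.34-fold. Without a detection filter the tryptophan list had a median of -0.14 (adjusted p = 0.109), and it also lost its call on ranks (0.126), with a floor of 64 (0.0650) and without the intensity trend (0.0736).

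Late embryogenesis abundant proteins and dehydrins, which protect drying cells, rose in 4 of 8 genes and fell in none (4 and 1 adjusted over the list alone), with a median log2 change of 2.42 (camera adjusted p = 4.743e-04, 0.462 with an estimated correlation). Beside RAB21, RAB16B (LOC4350453) rose 45.4-fold and RAB16C (LOC4350452) 14.2-fold. Without a detection filter the median of this list was 1.01. A further probe set of RAB21, used in the list because its mean log2 intensity is higher, was at least 155-fold higher. LEA19, outside the list, was at least 124-fold higher. Heat shock proteins and their factors rose in 21 of 76 genes and fell in 3 (21 and 5 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 7.859e-05, 0.462 with an estimated correlation). The medians in infested replicates 1 and 2 were 0.51 and 0.27. HSP24.1 (LOC4330786) rose 11.5-fold and HSP17.9A (LOC4332357) 8.49-fold. HSFA2C (LOC4348646) rose 28.4-fold on a probe set titled both as a heat shock factor and as a zinc finger protein, and its other probe set was at 116.5 in the control, where it was not detected, and at 1417.2 and 921 in infested stems. The dehydrin list lost its call with a floor of 64 (adjusted p = 0.0557) and on ranks (0.105).

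Cytochrome P450 genes rose in 18 of 97 cases and fell in 6 (19 and 8 adjusted over the list alone), with a median log2 change of 0.41 (camera adjusted p = 0.0284, 0.462 with an estimated correlation). CYP734A4 (LOC4341450), of a family that inactivates brassinosteroids, was at least 33.0-fold higher and CYP99A2 (LOC4335096), of the momilactone gene cluster, at least 15.9-fold. Auxin response genes rose in 6 of 21 cases and fell in none (6 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0165, 0.462 with an estimated correlation). The members that rose included GH3.2 (LOC4326893), at least 85.1-fold higher, and GH3-8 (LOC4343785), at least 8.53-fold higher, enzymes that join auxin to amino acids, and also JAR1, which acts on jasmonate. Among probe sets detected on all 3 arrays both lists lost their call (adjusted p = 0.180 for P450 and 0.386 for auxin), the auxin median being 0.01, and it was 0.53 and 0.08 in infested replicates 1 and 2. The P450 list also lost it without a detection filter (median 0.04, adjusted p = 0.150) and with a floor of 64 (0.0558), and the auxin list on ranks (0.0798) and with the floor (0.0680).

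**Figure D2:**
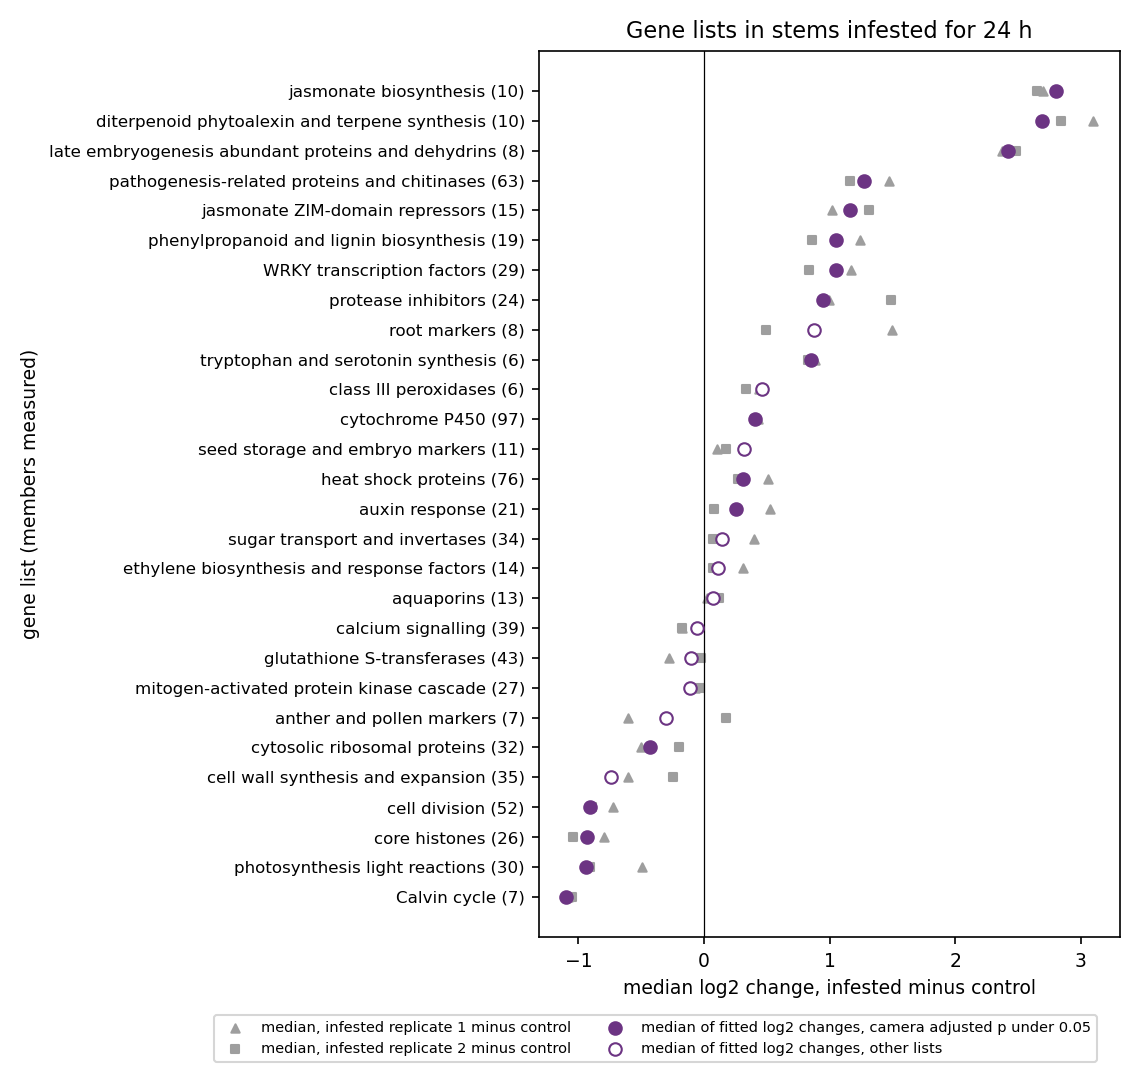
Median log2 change (x axis) of 28 gene lists (y axis, number of measured members in brackets), from the fit (circles) and in each infested replicate minus the control (grey triangles and squares). Filled circles are the 17 lists with a camera adjusted p under 0.05, from 2.80 for jasmonate biosynthesis to -1.10 for the Calvin cycle.

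Core histones, which package DNA, fell in 9 of 26 genes and rose in none (12 fell adjusted over the list alone), with a median log2 change of -0.93 (camera adjusted p = 1.114e-05, 0.462 with an estimated correlation). The title words of this list also let in histone H1, which is not a core histone. The histone H3 gene LOC4338913 was 9.69-fold lower, with 5733.1 in the control and 615.5 ± 241 (SD, n = 2) in infested stems, and a probe set titled histone H2B was 8.40-fold lower. Cell division genes fell in 7 of 52 cases and rose in none (4 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 4.743e-04, 0.462 with an estimated correlation). The kinesin KIN13B (LOC4326684), a motor protein of microtubules, was 3.20-fold lower.

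Photosynthesis genes fell in 8 of 30 cases and rose in 1 (10 and 1 adjusted over the list alone), with a median log2 change of -0.94 and a mean of -0.56 (camera adjusted p = 0.00876, 0.462 with an estimated correlation). In infested replicates 1 and 2 the medians were -0.50 and -0.91. The photosystem II subunit gene LOC4324933 was 3.63-fold lower and the photosystem I gene LOC4342404 2.92-fold lower. The member that rose was at least 99.0-fold higher, and its title gives only weak similarity to a photosystem protein. In the Calvin cycle list 4 of 7 genes fell and none rose (4 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.0231, 0.462 with an estimated correlation). Beside rbcS, the sedoheptulose-1,7-bisphosphatase LOC4335227 was 2.82-fold lower. The further probe set titled as the small subunit of Rubisco, at 41527.3 in the control, was 2.34-fold lower. That probe set lost its call without a detection filter (limma adjusted p = 0.144). It also did so without the intensity trend among probe sets detected on all 3 arrays (limma adjusted p = 0.0604). Cytosolic ribosomal proteins had a median of -0.43 (camera adjusted p = 0.0283, 0.660 with an estimated correlation), and 1 of 32 genes fell and none rose (none when adjusted over the list alone). It was the 40S protein S5 gene LOC4326457, 2.30-fold lower. The ribosomal medians were -0.50 and -0.20 in infested replicates 1 and 2. With a floor of 64 the photosynthesis and Calvin cycle lists lost their calls (adjusted p = 0.0680 and 0.0676). The Calvin cycle list also lost it without a detection filter (0.111), on ranks (0.0798) and without the intensity trend (0.0736).

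The other 11 lists did not pass camera, though single members changed. Sugar transport and invertase genes rose in 6 of 34 cases and fell in 3 (7 and 3 adjusted over the list alone; camera adjusted p = 0.276). The sugar transporter SWEET1a (LOC4324848) was 7.09-fold lower and the cell wall invertase CIN1 (LOC4329561) rose 2.97-fold. Glutathione S-transferases rose in 8 of 43 cases and fell in 6 (8 and 6 adjusted over the list alone; camera adjusted p = 0.959), with a median of -0.10 (-0.28 and -0.03 in infested replicates 1 and 2) and a mean of 0.03. LOC4349188 rose 9.60-fold, while LOC4349192, titled GSTU7, was 11.3-fold lower and LOC4349191, titled GSTU14, 36.4-fold lower. Cell wall genes rose in 5 of 35 cases and fell in 4 (5 and 6 adjusted over the list alone; camera adjusted p = 0.304): the beta-expansins EXPB6 (LOC4349347) and EXPB7 (LOC4331300) rose 5.09-fold and 5.30-fold, while the xyloglucan endotransglycosylase LOC4336904 was at least 27.3-fold lower. Ethylene genes rose in 3 of 14 cases and fell in 1 (3 and 1 adjusted over the list alone; camera adjusted p = 0.536), among them the ACC synthase ACS2 (LOC4336750), at least 4.86-fold higher. MAP kinase genes rose in 4 of 27 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.420), with a median of -0.11 (-0.07 and -0.03 in infested replicates 1 and 2, 0.01 with detection on all 3 arrays) and a mean of 0.09. MPK3 (LOC4332475) rose 2.46-fold, MPK6 (LOC4340170) had a log2 difference of -0.15 ± 0.31 (SE), and the members WNK7 and WNK8 are kinases outside the cascade.

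Calcium signalling genes rose in 3 of 39 cases and fell in 2 (1 and 2 adjusted over the list alone; camera adjusted p = 0.668), with a median of -0.06 that was -0.18 in each infested replicate and 0.03 with quantile normalization. Aquaporins rose in 2 of 13 cases (2 adjusted over the list alone; camera adjusted p = 0.271), and the water channel PIP2;4 (LOC4343119) was at least 85.4-fold higher. Of the 6 genes in the peroxidase list, 1 fell (2 rose and 1 fell adjusted over the list alone), LOC4350051, which was 4.48-fold lower. Its median was 0.46 (0.11 with undetected genes at their bound, -0.07 at a mean intensity of at least 64) while camera took the direction as down (adjusted p = 0.959), and fry gave an adjusted p of 0.0414 for a fall. The salicylate regulator NPR1 (LOC4327315; adjusted p = 0.205) and WRKY24 (LOC4327518; adjusted p = 0.196) did not pass the test.

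**Figure D3:**
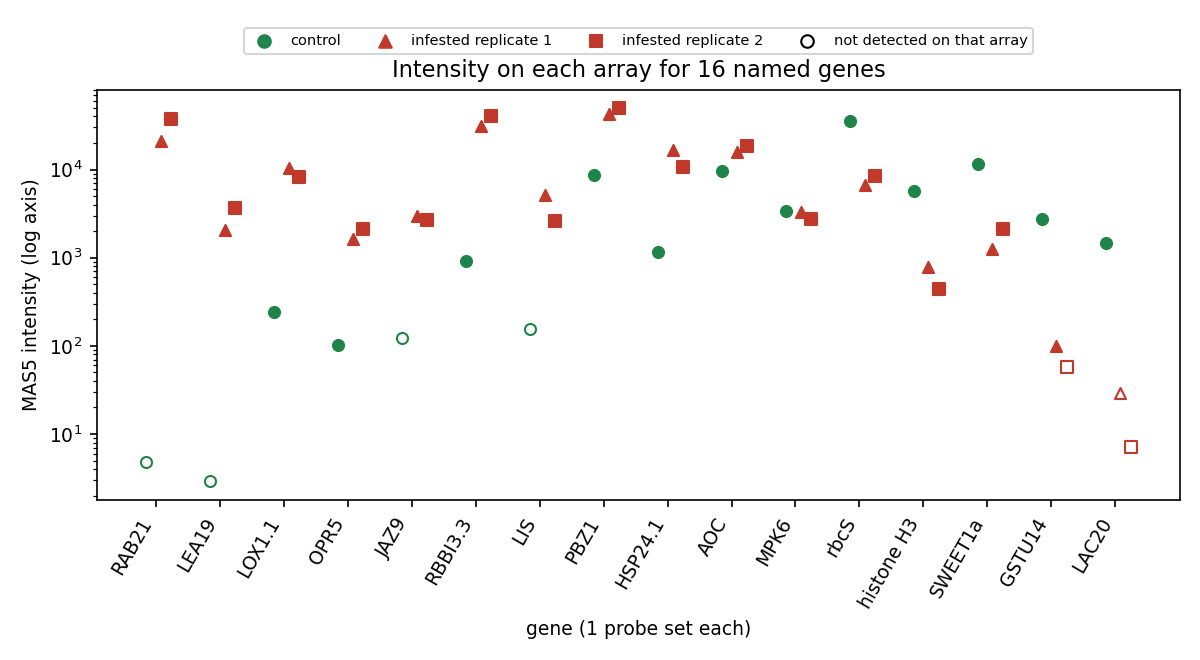
Intensity on each array (y axis, log scale) of 16 named genes (x axis), for the control (green circles) and infested replicates 1 and 2 (red triangles and squares), with open symbols where the probe set was not detected. RAB21 was at 4.8 in the control and at 21300.6 and 37474.1 in infested stems, while rbcS was at 35965.7 in the control and lower in both infested replicates.

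Among the largest rises in log2, the dehydrin RAB21 stood first, and LOC4325841 and LOC4351197, which have no descriptive title, were at least 602-fold and 348-fold higher. LOC4337276 was at least 1010-fold higher, with the synonym OsPP2C45, while the deposited title reads chitinase. Its other probe set was at 1988.4 in the control and at 4764.9 and 4781.4 in infested stems. LOC4344618, titled a 33 kDa secretory protein, was at least 81.4-fold higher and OsPM19L1 (LOC4338635) at least 66.9-fold. The control values behind this order were not detected, and the bounds give another order. The chitinase LOC4351188, not among the largest rises in log2, was at least 149-fold higher. The largest fall among the named genes was that of the laccase LAC20 (LOC4351006), at least 50.6-fold, from 1486.8 to 18.05 ± 15.5 (SD, n = 2). LOC9266169 was 23.7-fold lower from a control intensity of 32863.5.

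The tissue field of all 3 samples reads dechorionated embryo, a term for animal embryos, which differs from the rice stem named as their source. Markers of other tissues were therefore examined. Their changes between infested and control stems cannot test a field that all 3 arrays share. Seed storage and embryo genes rose in 1 of 11 cases and fell in none (1 adjusted over the list alone; camera adjusted p = 0.475), with a median log2 change of 0.32 that was 0.10 and 0.18 in infested replicates 1 and 2 and -0.08 without a detection filter. The member that rose was a 16 kDa oleosin (LOC4336570), at least 8.84-fold higher, with 37.4 in the control. Glutelin LOC4334103 was at 2424.8 in the control and 3311 ± 799 (SD, n = 2) in infested stems. Anther and pollen genes fell in 1 of 7 cases (1 adjusted over the list alone; camera adjusted p = 0.452), with medians of -0.60 and 0.18 in infested replicates 1 and 2. Root genes rose in 2 of 8 cases (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0938), and the list passed with all probe sets of a gene (median 1.19, adjusted p = 0.0133); these were the PR10 protein LOC4352487, also in the list of pathogenesis-related proteins, and LOC4333923. The ratio of the 3′ to the 5′ probe set, a measure of RNA integrity, was 4.23, 4.28 and 3.43 for actin in the control and infested replicates 1 and 2, and 4.36, 2.16 and 3.44 for GAPDH. In the same order it was 2.04, 2.44 and 2.18 for cyclophilin and 0.571, 0.549 and 0.565 for ubiquitin. Over the probe sets detected on all 3 arrays, Pearson's r across probe sets, which are not independent replicates, was 0.954 between the infested arrays and 0.798 and 0.834 between each of them and the control.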

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

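The pairing of no intensity trend with detection on all 3 arrays, and the setting with a mean intensity of at least 64, were chosen after seeing the data. The 4260 probe sets past the limma threshold became 3682 with quantile normalization (2072 rose, 1610 fell), 4088 with median centring, 4374 with 16 added, 3451 without a detection filter, 3508 with detection on all 3 arrays, 4052 with a robust variance, 4035 at a mean intensity of at least 64 and 4241 with a 2-fold limit as well. Of the 3682, 3644 were also among the 4260. With a floor of 64 the count was 0 (0 rose, 0 fell; 5879 at an unadjusted p under 0.05), as it was without the intensity trend (0 rose, 0 fell; 5276 unadjusted), where prior degrees of freedom fell to 1.28 and 2.31 from 12.0. Without the trend but with detection on all 3 arrays it was 2657 (1271 rose, 1386 fell); the cause was not tested. The 6185 probe sets at least 2-fold in both infested arrays became 15179 without a detection filter (7206 higher, 7973 lower; 57258 probe sets counted in place of 27446), 3450 with detection on all 3 arrays (1630, 1820; 18986 counted) and 3164 at least 3-fold (1841, 1323). Leaving out 1 infested array, so that 1 array and not both had to pass, gave 8967 to 9387, with 3942 to 4350 higher and 5025 to 5037 lower. The 17 lists past camera (12 up, 5 down) became 11 with a floor of 64 (8 up, 3 down) and 0 with an estimated correlation (0 up, 0 down). With fry, which does not compare a list with other genes, the count was 1 (0 up, 1 down). Camera with an estimated correlation and fry rest on 1 residual degree of freedom and have little power. Their losses thus do not tell correlated genes from too few arrays. The cause was not tested for the floor. The count was 13 on ranks, 14 without a detection filter, 14 of 25 lists with detection on all 3 arrays, 15 without the trend, 18 with all probe sets of a gene and 17 under the scalings, 16 added and the robust variance. Among 254 lists and named probe sets, 179 lost their call with the floor, 176 without the trend, 14 without a detection filter, 7 with quantile normalization, 5 with a robust variance, 1 with median centring and, of the 188 measured there, 2 with detection on all 3 arrays, and the median of the tryptophan and serotonin list changed sign without a detection filter, from 0.854 to -0.139 (adjusted p = 0.109), the only called list or gene whose value reversed. Of the 188 measured with detection on all 3 arrays, 19 lost their call without the trend. At a mean intensity of at least 64, 3 lost it. Of the lists, 24 lost it with an estimated correlation, 24 with fry and 4 on ranks. Signal over background limits dim probe sets: of those at an intensity under 100 the median standard error was 1.31. No paired analysis was possible because the control has 1 array.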

Other observations

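The tests of seed tissue, of the control array, of scaling and of green cells, and the 15 gene families named here other than the diterpenoid list, were chosen only after the main results were seen. Of the 16 added lists, 7 passed camera, adjusted among the 16. Clade A protein phosphatases 2C, negative regulators of abscisic acid signalling that the hormone induces, rose in 5 of 7 genes and fell in none (5 adjusted over the list alone), with a median log2 change of 1.18 (camera adjusted p = 3.944e-05, 0.619 with an estimated correlation). PP2C68 was at least 32.0-fold higher, PP2C51 (LOC4339671) at least 9.21-fold, and PP2C30 (LOC4332374) rose 11.7-fold, from 674.3 to 7898 ± 2.33 (SD, n = 2). Genes of glycolysis and fermentation rose in 6 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 9.382e-04, 0.619 with an estimated correlation): the pyruvate decarboxylase PDC1 (LOC4339066) was at least 39.0-fold higher and the alcohol dehydrogenase Adh2 (LOC4350054) rose 3.75-fold. NAC transcription factors rose in 8 of 20 cases and fell in 1 (8 and 1 adjusted over the list alone), with a median of 1.48, or 1.05 with undetected genes at their bound (camera adjusted p = 6.409e-04, 0.744 with an estimated correlation), among them NAC4 (LOC4327485), which rose 8.92-fold. ABC transporters rose in 10 of 39 cases and fell in 2 (10 and 3 adjusted over the list alone), with a median of 0.55, or 0.49 at their bounds (camera adjusted p = 3.492e-04, 0.619 with an estimated correlation). ABCG45 (LOC4346210) was at least 75.7-fold higher and ABCG36 (LOC4327728) rose 15.9-fold. The diterpenoid phytoalexin genes rose in 4 of 13 cases and fell in none (7 adjusted over the list alone), with a median of 3.05, or 2.62 at their bounds (camera adjusted p = 1.63e-04, 0.619 with an estimated correlation), among them KSL10 (LOC4352248), at least 16.4-fold higher. Without a detection filter the medians were 0.15 for NAC factors, 0.21 for ABC transporters and 0.35 for glycolysis and fermentation, the NAC median was 1.72 and 0.93 in infested replicates 1 and 2, and with a floor of 64 it was 0.70 and the diterpenoid median 1.33.

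Tubulins fell in 8 of 16 genes and rose in none (10 fell adjusted over the list alone), with a median log2 change of -1.14 (camera adjusted p = 3.944e-05, 0.619 with an estimated correlation). The beta-tubulin TUB8 (LOC4333632) was 7.06-fold lower and TUB6 (LOC4338790) 3.58-fold, with 8620.4 in the control and 2411 ± 238 (SD, n = 2) in infested stems. Genes of chlorophyll synthesis fell in 3 of 6 cases and rose in none (4 fell adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.0160, 0.619 with an estimated correlation), among them the protoporphyrinogen oxidase PPOX1 (LOC4327918), 4.68-fold lower, and the list lost its call without the intensity trend (adjusted p = 0.0507). The other 9 lists did not pass camera, though proline and polyamine synthesis passed without a detection filter (adjusted p = 0.0170) and with all probe sets of a gene (0.0328), and receptor-like kinases without the intensity trend (0.0411). With an estimated correlation camera gave both of these lists an adjusted p of 0.741. MYB factors rose in 6 of 56 cases and fell in 4 (6 and 4 adjusted over the list alone; camera adjusted p = 0.821), with a median of -0.03 (0.07 and -0.04 in infested replicates 1 and 2) and a mean of 0.03, and JAMYB (LOC4351131), known to be induced by jasmonate, rose 24.4-fold. Receptor-like kinases rose in 6 of 44 cases and fell in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.166), disease resistance proteins in 7 and 3 of 108 (5 and 3; 0.598) and basic helix-loop-helix factors in 3 and 1 of 26 (3 and 2; 0.988). Lipid transfer proteins rose in 5 of 23 cases and fell in 5 (8 and 8 adjusted over the list alone; 0.965), with a median of -0.50 (-0.19 and -0.46 in infested replicates 1 and 2, -0.11 with detection on all 3 arrays) while camera took the direction as up. Trehalose and raffinose synthesis genes rose in 1 and fell in 1 of 10 cases (1 and 1 adjusted over the list alone; camera adjusted p = 0.258): the raffinose synthase LOC4325200 rose 7.08-fold and the phosphatase TPP1 (LOC4330221) was 2.89-fold lower. In proline and polyamine synthesis 1 of 7 genes rose (1 adjusted over the list alone; camera adjusted p = 0.167), the S-adenosylmethionine decarboxylase LOC4329955, by 3.73-fold, while P5CS1, of proline synthesis, had a log2 difference of 0.32. Amino acid transporters rose in 1 of 9 cases (1 adjusted over the list alone; camera adjusted p = 0.777), with a median of -0.21 while camera took the direction as up. Of 43 proteasome genes none changed by limma, the smallest unadjusted p being 0.0680 and the smallest adjusted p 0.231, and camera gave an adjusted p of 0.777.

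The dehydrins RAB21, RAB16B and RAB16C rose, in a list of which 4 of 8 genes rose. The tissue field of the samples, dechorionated embryo, does not go with rice stem, but the control has the same field. It thus gives no ground for seed tissue in the infested samples alone. Seed tissue in the infested samples would bring storage proteins, and the seed storage and embryo list had a median log2 change of 0.32 (0.317; SD over members 1.25; 0.10 and 0.18 in infested replicates 1 and 2, -0.08 without a detection filter) beside 2.42 for the dehydrin list (1.01 without the filter); with that spread, an oleosin that rose and a glutelin already at 2424.8 in the control, seed tissue cannot be told apart from a response. A response of the abscisic acid type stays open as well: the clade A phosphatases had a median of 1.18, which is consistent with it, and abscisic acid was not measured. A low dehydrin level in the 1 control array for reasons other than infestation cannot be told apart from a response either, because there was no other control array. Infestation itself stays open.

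Of core histones 9 of 26 genes fell, of cell division genes 7 of 52 and of photosynthesis genes 8 of 30. The 3 lists passed camera but not with an estimated correlation (adjusted p = 0.462), a test on 1 residual degree of freedom with little power. MAS5 scaling pulled down by very bright rises would bring the lists near 0 under another scaling, but the median closest to 0 under median centring or quantile normalization was -0.79 (-0.788), which argues against scaling as the cause. A lower share of green cells would lower transcripts made only in green cells by 1 factor. The log2 changes of 28 bright photosynthesis and Calvin cycle members had an SD of 0.819 beside a median standard error of 0.358, with a range of -2.26 to 0.87. These values argue against a lower share of green cells as the whole cause only if all 28 are made in green cells alone, which lists filled by titles do not ensure. The standard error also assumes that the control varies like the infested arrays, and saturation of bright probe sets could add to the spread. A lower share of dividing cells in the infested stems and an effect of infestation on these genes stay open and were not tested. High levels in the 1 control array for reasons other than infestation cannot be told apart from them either. There was no other control array, which limits every list in the same way.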
